A study of Mus musculus with 6 samples.

How the data were processed

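Bulk RNA libraries of 6 samples of sorted intestinal fibroblasts were analysed, 3 wild-type and 3 DdblGata1, grouped by the genotype in the labels. Per the labels, intestines of pups at postnatal day 9 were freed of epithelium with 10 mM EDTA for 30 min at 37 °C and digested 3 times for 20 min with Liberase and DNase. CD45-negative, EpCAM-negative, CD31-negative and podoplanin-positive cells were sorted into lysis buffer, and stranded libraries were made from 100 ng of total RNA. The submitters' notes name bcl2fastq 2.2, kallisto, R 4.2.2 and DESeq2 with the builds mm10 and GRCm38.p6. Which tool did which step is not given in the sources used here.

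The deposited gene table holds estimated counts (expected counts) rounded to whole numbers for 15238 genes, 14807 of them protein-coding. Each gene of it has at least 10 counts in at least 3 libraries, so the authors had removed genes with fewer. It was checked against the deposited transcript files, in which the authors give kallisto's estimated counts (expected counts), TPM and other values, namely effective transcript lengths in bases, for 115270 transcripts. Of the gene table's values, 99.7% equalled TPM summed per gene, multiplied by the gene's mean transcript length and scaled to the library total, within 1% plus 1 count. Plain sums of estimated counts matched for 26.3%. The table was therefore read as length-scaled and not scaled between libraries. Transcripts were assigned to genes with GENCODE mouse M21, which placed 113492 of them, and 15223 of the table's genes were found this way. 11 gene names belong to more than 1 identifier. The deposited sample sheet gives a size factor per library as a ratio around 1 and, as a score, 2 surrogate variables per library, whose method is not given in the sources used here. Total estimated counts over transcripts were 28214500 to 31326210 per library, and the gene table held 99.6% of them in each. A count of 0 was taken to allow up to 3 counts, which covers counting error only. Mean fragment length was read from the difference between length and effective length of 5052 transcripts of at least 2000 bases without counts.

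Genes were compared with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr (which removed no gene), robust quasi-likelihood fits and Benjamini-Hochberg adjustment at 0.05. No covariate was used, since the labels name no batch, sex or litter. CPM are TMM-scaled means with SD, and fold changes are fitted log2 values, DdblGata1 minus wild-type, with SE. For gene lists, camera of limma 3.58.1 was run with a preset inter-gene correlation of 0.01 on 54 lists fixed before the data were examined, 51 of which had at least 3 measured genes. Members were also counted by edgeR adjusted over the list alone, and the mean log2 CPM (prior count of 2) of each list was compared by an exact two-sided permutation test, whose smallest p is 0.1. Transcript usage was tested with diffSpliceDGE on rounded transcript counts of 9447 genes with 2 or more transcripts (33127 transcripts) and the Simes method. Principal components used the 500 most variable genes and, for comparison, all genes.

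The genes named were chosen by a rule fixed before the data were examined. It takes Gata1, Xist and 4 Y-linked genes. Among genes past the threshold with non-overlapping groups and a mean log2 CPM of at least 1, it takes up to 12 per side. Where fewer than 6 pass, it takes 6 per side by smallest p under the same limits on overlap and CPM, as values only. It further takes up to 4 members per described list by smallest p and 6 genes for transcript usage. A few members beyond these are named because they passed when adjusted over the list alone or, as for Acta2, are the best known of their list; they were chosen after their values were seen. The results of a few genes that the rule takes are not reported.

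Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, limma-trend on log2(TPM + 1), other scalings and filters, a length offset, a minimum fold of 1.2, no genes on the X and Y chromosomes, an estimated correlation, fry, lists without shared genes, the F test and a 10% share filter for transcripts, and leaving out each library in turn. Unscaled transcript sums, the deposited surrogate variables and fragment length as covariates, and DESeq2 without each library were added after the data were seen. The edgeR and DESeq2 gene tests, camera with the preset and the estimated correlation, and diffSpliceDGE were repeated for all 10 splits of the 6 libraries into 3 and 3. Sex was not used as a covariate: Xist had no transcript in the index, and 0 to 2 counts of Ddx3y and 0 of Eif2s3y gave no contrast between libraries.

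The tests were also run on simulated data of the same size and dispersion. edgeR recovered 0 of 50 genes changed 1.5-fold, 14 of 50 changed 2-fold, 42 of 50 changed 4-fold and 44 of 50 changed 8-fold, with 7 false calls. DESeq2 recovered 6, 28, 44 and 47 of these, with 28 false calls. In simulated lists of independent genes, camera recovered 5 of 5 lists at 1.3-fold and 5 of 5 at 1.6-fold. It made 0 false calls among the unchanged lists of the 40 tested. At the observed dispersion of transcripts, diffSpliceDGE recovered 0 of 67 genes at 2-fold, 1 of 67 at 4-fold and 3 of 66 at 8-fold. It made 20 false calls among the unchanged genes of the 9447 tested. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.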

Results

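RNA was sequenced in bulk from podoplanin-positive fibroblasts sorted from the intestine of Balb/c pups at postnatal day 9. The sort kept cells negative for CD45, EpCAM and CD31, the surface markers of leukocytes, epithelium and endothelium. Of the 6 libraries, 3 came from wild-type pups (replicates 1, 3 and 4) and 3 from DdblGata1 pups (replicates 4, 9 and 10). In DdblGata1 animals a promoter element of Gata1, a transcription factor of blood cell development, is deleted, and eosinophils are lacking. The series title places the comparison within the question of whether eosinophils promote a postnatal wave of smooth muscle differentiation in the villi. The total estimated counts over 15238 genes were 31018196, 30210644 and 31210800 in wild-type replicates 1, 3 and 4. They were 28110454, 29101736 and 30993472 in DdblGata1 replicates 4, 9 and 10. The labels do not say that each library came from a separate animal. The p-values of the gene and transcript tests therefore measure the spread between these libraries only. Camera with its preset correlation compares the genes of a list with all other genes. Its p-values do not take into account how members of a list varied together between these libraries. The tests of gene positions further below likewise count genes rather than libraries.

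Transcripts of Gata1 itself (ENSMUSG00000031162, GRCm38 chromosome X, 7959260 to 7978071) had an estimated count of 1 in wild-type replicate 1 and 0 in the other 5 libraries. A count of 0 allows up to 0.106 CPM (counts scaled to the library total) at the lowest depth, so these fibroblasts gave no measure of the deletion. Among Y-linked genes, Eif2s3y had 0 estimated counts in all 6 libraries and Ddx3y had 0 to 2. Kdm5d ranged from 22.2 to 70.6 and Uty from 2.44 to 21.1 estimated counts, and both genes have close relatives on the X chromosome. No transcript of Xist was present in the transcript index used for counting.

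The 6 libraries did not separate by genotype along the first 2 principal components. The first principal component of the 500 most variable genes carried 38.7% of the variance. It placed wild-type replicate 1 at -33.9 and DdblGata1 replicate 10 at 29.9, with the other 4 libraries between -15.5 and 20.4. The second component carried 23.8% and placed wild-type replicate 4 (19.7) and DdblGata1 replicate 4 (21.4) together at one end. Component 3 (14.3%) overlapped too, with -11.8, -20.8 and 3.8 in wild-type replicates 1, 3 and 4 and 8.0, 20.0 and 0.8 in DdblGata1 replicates 4, 9 and 10. Over all genes component 3 carried 15.6% and did separate the genotypes, with -1.6, -46.7 and -2.9 in wild-type and 29.9, 17.5 and 3.8 in DdblGata1 libraries, where chance separates 10% of components. Wild-type replicate 4 and DdblGata1 replicate 4 were also the closest pair, with a Pearson correlation of 0.976 across genes. The lowest correlation, 0.925, was between wild-type replicate 1 and DdblGata1 replicate 10. Genes are not independent replicates, and the correlations were not tested. The mean fragment length was 364, 329 and 364 bases in wild-type replicates 1, 3 and 4. It was 363, 341 and 326 bases in DdblGata1 replicates 4, 9 and 10. Mitochondrially encoded genes took 5.95%, 5.92% and 4.11% of the counts in the wild-type libraries and 3.40%, 3.96% and 4.76% in the DdblGata1 libraries, in the same order.

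**Figure D1:**
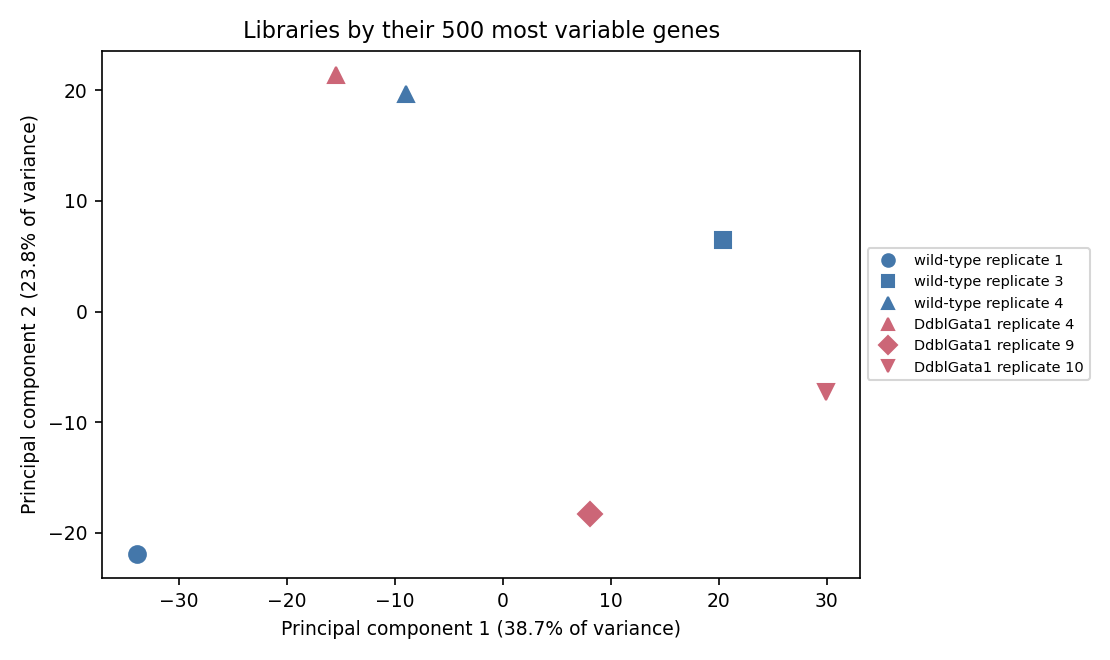
Principal components of the 500 most variable genes (log2 CPM), first component on the horizontal axis (38.7% of the variance) and second on the vertical axis (23.8%), 1 point per library. Wild-type replicate 4 and DdblGata1 replicate 4 lie close together, and wild-type replicate 1 lies at the far left.

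The comparison of DdblGata1 with wild-type fibroblasts asked which genes differ when eosinophils are lacking. Fgf10, a growth factor made by mesenchyme, had 18.1 ± 5.68 CPM (SD, n = 3) in wild-type and 67.0 ± 10.1 in DdblGata1 libraries. Its log2 fold change, DdblGata1 minus wild-type, was 1.89 ± 0.26 (SE). Emilin2, an extracellular matrix glycoprotein, had 125 ± 34.1 and 284 ± 16.2 CPM, with a log2 fold change of 1.18 ± 0.21. The nuclear body component Sp100 had 13.1 ± 1.88 and 34.7 ± 3.39 CPM (log2 fold change 1.41 ± 0.18). Neto1, an auxiliary subunit of glutamate receptors, had 1.94 ± 1.29 and 17.2 ± 5.69 CPM (3.15 ± 0.54). Fkbp1b, which binds ryanodine receptors, and the splicing factor gene Mfap1a had log2 fold changes of 1.53 ± 0.25 and 0.98 ± 0.15. On the lower side, Mgll, the monoacylglycerol lipase, had 169 ± 6.25 CPM in wild-type and 103 ± 3.57 in DdblGata1 libraries (-0.72 ± 0.12). Arhgap19 had a log2 fold change of -2.44 ± 0.43, and the zinc finger gene Zfp781 had -2.30 ± 0.35. Values of -1.07 ± 0.22 for Nptx2, -1.03 ± 0.21 for Tppp and -1.01 ± 0.21 for Cap2, a regulator of actin, completed the lower side. On GRCm38, Fgf10 (ENSMUSG00000021732) lies on chromosome 13 from 118669791 to 118792115, and Sp100 (ENSMUSG00000026222) on chromosome 1 from 85649988 to 85709998. Emilin2 (ENSMUSG00000024053) lies on chromosome 17 from 71252172 to 71311978, and Mgll (ENSMUSG00000033174) on chromosome 6 from 88724412 to 88828360. Mfap1a has a near-identical relative, Mfap1b, whose reads are hard to assign, so its value is uncertain.

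These 12 genes were taken by the smallest unadjusted p in edgeR, 6 per side, because no gene passed its test. Only genes with non-overlapping groups could be taken, so their separation is not a result. The quasi-likelihood test of edgeR called 0 of 15238 genes at an adjusted p of 0.05, and the adjusted p of all 12 genes was 0.384, the lowest of any gene. By the same test, 1564 genes had an unadjusted p under 0.05, 919 of them higher and 645 lower in DdblGata1 libraries. That count was 2715 without DdblGata1 replicate 4, 1000 without DdblGata1 replicate 9 and 818 without DdblGata1 replicate 10, and its balance was 940 higher and 921 lower with the 2 deposited surrogate variables and 1252 and 374 by limma on TPM. DESeq2 called 214 genes, 142 higher and 72 lower, but 82 and 83 without wild-type replicate 4. The 12 named genes were among them, with DESeq2 adjusted p-values from 7.69e-08 for Sp100 and 1.73e-07 for Fgf10 to 0.0056 for Cap2. In simulated data DESeq2 made 28 false calls against 7 by edgeR, more than its threshold allows. DESeq2 calls with an adjusted p near 0.05, here and below, are therefore uncertain. In 2487 genes, or 16.3%, the values of the 2 genotypes did not overlap, where chance gives 10% on average. Genes vary together, so a single grouping can lie far from that average. The share in the other splits was not counted. Without DdblGata1 replicate 4, edgeR called 1 gene, Il6 (log2 fold change 2.41, adjusted p 0.043), which was singled out after its values were seen. The DESeq2 count moved with single libraries: it was 1025 without DdblGata1 replicate 4 (537 higher and 488 lower), 84 without DdblGata1 replicate 9, 43 without DdblGata1 replicate 10 and 106 without wild-type replicate 1. With the 2 deposited surrogate variables as covariates DESeq2 called 449 genes (215 higher and 234 lower), 180 of them among the 214 and all 180 in the same direction.

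**Figure D2:**
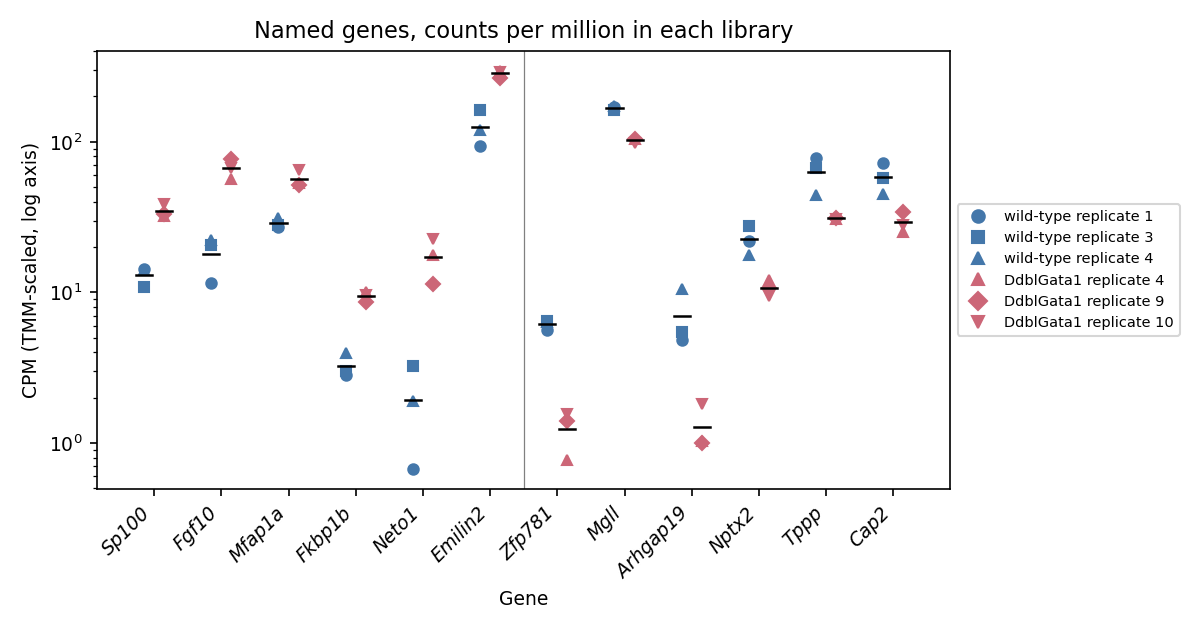
TMM-scaled CPM (log axis) of the 12 named genes, 1 point per library, with a bar at each group's mean (n = 3). They have the smallest unadjusted p, 6 per side, among genes whose groups do not overlap. Fgf10 and Sp100 lie higher in every DdblGata1 library than in any wild-type library, and Mgll lies lower in every one, as the choice required.

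Genes of the smooth muscle contractile apparatus were lower in DdblGata1 libraries. Of the 22 genes in this list, 21 had a lower value, with a median log2 fold change of -0.62. Des, the intermediate filament protein of muscle, had 861 ± 181 CPM (SD, n = 3) in wild-type and 505 ± 74.2 in DdblGata1 libraries. The actin crosslinker Flna had 3995 ± 1349 and 2195 ± 282 CPM. Synm, a partner of desmin, and Csrp1, a cytoskeletal regulator, had log2 fold changes of -0.79 ± 0.22 and -0.66 ± 0.19 (SE). The value of Acta2, smooth muscle actin, was -0.80. The competitive set test camera called the list lower, with an adjusted p of 1.49e-11 (adjusted p = 0.602 with an estimated correlation). By edgeR, 10 members were lower and 0 higher at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. DESeq2 called 3 members lower, Des (adjusted p 0.0303), Synm (0.0442) and Flna (0.0442), and 15 with the surrogate variables. Mean log2 CPM of the list was 8.99, 8.93 and 8.38 in wild-type replicates 1, 3 and 4, and 7.90, 8.48 and 8.25 in DdblGata1 replicates 4, 9 and 10, so the groups overlapped.

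Targets of serum response factor (SRF) and other actin cytoskeleton genes were lower as well, by less. Of 23 measured genes 19 had a lower value, and the median was -0.21. Srf, which encodes the transcription factor itself, had 73.1 ± 10.6 CPM (SD, n = 3) in wild-type and 42.2 ± 6.69 in DdblGata1 libraries (log2 fold change -0.79 ± 0.18, SE). It was the 1 member that fell when adjusted over the list alone (edgeR adjusted p 0.0462). Actn1, an actin crosslinker, had a log2 fold change of -0.58 ± 0.15, and DESeq2 called both Srf (adjusted p 0.0146) and Actn1 (0.0274) lower. Tgfb1i1 and Fhl2, focal adhesion proteins, had values of -0.51 and -0.38. Camera called the list lower with an adjusted p of 4.42e-04 (adjusted p = 0.602 with an estimated correlation). At an unadjusted p under 0.05, 6 members were lower and 1 higher.

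**Figure D3:**
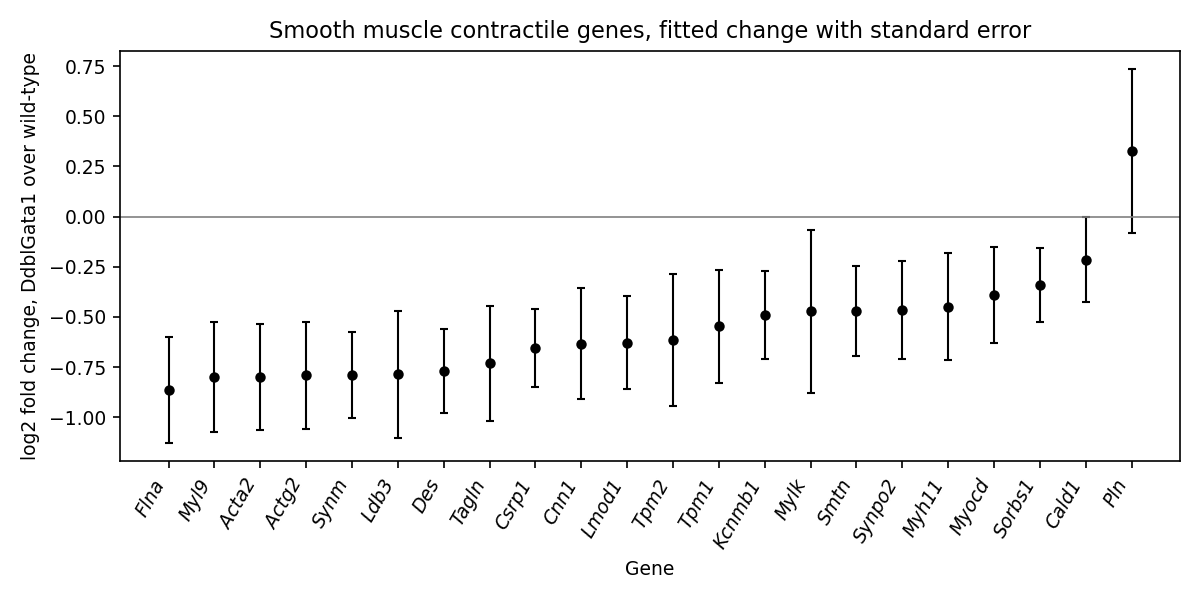
Log2 fold change (DdblGata1 minus wild-type, n = 3 per group) of each of the 22 genes of the smooth muscle contractile list, with bars of 1 SE from edgeR. The values of 21 genes lie below 0.

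Among fibroblast subtypes, markers of PDGFRA-high villus fibroblasts and telocytes were lower in DdblGata1 libraries, with a median log2 fold change of -0.48 over 18 genes. Frzb, a secreted Wnt antagonist, had 33.0 ± 2.60 CPM (SD, n = 3) in wild-type and 18.8 ± 4.91 in DdblGata1 libraries, and DESeq2 called it lower (adjusted p 0.0442). Foxf1, a transcription factor of gut mesenchyme, had a log2 fold change of -0.61 ± 0.17 (SE), and the matrix proteins Tgfbi and Tnc had -0.55 ± 0.18 and -0.80 ± 0.31. Camera called the list lower with an adjusted p of 0.00237 (adjusted p = 0.451 with an estimated correlation), and of 0.0867 without genes that other lists share. Members at an unadjusted p under 0.05 in edgeR were 7 lower and 1 higher, and 0 passed when adjusted over the list alone. Pericyte and vascular mural markers were also called lower (camera adjusted p 0.0019; adjusted p = 0.451 with an estimated correlation). When adjusted over the list alone, Gucy1a1, Kcnj8, Rgs5 and Cspg4 fell, by 0.55, 0.62, 0.59 and 0.58 on the log2 scale, and Ebf1, a transcription factor of several mesenchymal cell types, rose by 1.33 (adjusted p 0.0389 for each by edgeR). DESeq2 called 1 of them, Gucy1a1 (adjusted p 0.0393). The list of markers of interstitial cells of Cajal, the pacemaker cells of gut muscle, was called lower by camera (adjusted p 4.77e-04; adjusted p = 0.602 with an estimated correlation). Cacna1h, a calcium channel subunit, had 70.2 ± 16.0 and 24.9 ± 15.6 CPM, and it fell with Elovl6 when adjusted over the list alone (edgeR adjusted p 0.0393 for both). DdblGata1 replicate 4 had the lowest level of this list, 5.46 against 6.44 to 7.07 in the other 5 libraries, and without it the camera adjusted p was 0.121.

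Markers of CD81-positive trophocytes and PDGFRA-low fibroblasts, which lie around the crypt and deeper in the wall, moved apart from each other. When adjusted over the list alone, 4 of 19 rose and 4 fell by edgeR. Dpp4, a surface peptidase of fibroblast progenitors, rose from 76.8 ± 25.1 to 246 ± 97.2 CPM (SD, n = 3; log2 fold change 1.68, adjusted p 0.00815). Cd55, a complement regulator, rose from 112 ± 15.3 to 217 ± 35.1 CPM (0.96, adjusted p 0.00815), and Cd34 (0.79) and Clec3b (0.67) rose with adjusted p-values of 0.0494. The Wnt amplifier Rspo2 fell by 0.95 on the log2 scale (adjusted p 0.0264), and Fgfr2 and Ackr4 fell too (0.0494 for both). DESeq2 called Cd55 and Dpp4 higher and Rspo2 lower. Camera did not call the list (adjusted p 0.177, upward), but did so without wild-type replicate 4 (0.0378) and without DdblGata1 replicate 9 (0.0257), both with the preset correlation (adjusted p 0.737 with an estimated one and all 6 libraries).

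Inflammatory cytokines and chemokines were higher in DdblGata1 libraries, with a median log2 fold change of 0.67 over 22 genes. When adjusted over the list alone, 10 rose and 1, Cxcl16, fell by edgeR. The chemokine Cxcl1 rose from 31.7 ± 6.08 to 102 ± 49.9 CPM (SD, n = 3), Ccl2 from 6.59 ± 1.66 to 22.3 ± 10.9 and Cxcl10 from 4.69 ± 0.340 to 12.6 ± 4.16. Il1r1, the interleukin-1 receptor, rose from 52.7 ± 6.30 to 87.7 ± 7.83 CPM (adjusted p 0.0113 over the list alone for each of these 4). DESeq2 called 8 members higher over all genes. Camera called the list higher with an adjusted p of 1.40e-07 (adjusted p = 0.451 with an estimated correlation). DdblGata1 replicates 9 and 10 had mean log2 CPM of 4.74 and 4.54, DdblGata1 replicate 4 had 4.10, and the wild-type libraries had 3.72, 3.93 and 3.96.

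Immediate early genes, which include those induced when tissue is dissociated, were higher as well. Of 24 measured genes 22 had a higher value, 16 of them at an unadjusted p under 0.05. Zfp36, which degrades cytokine messages, had 380 ± 31.2 CPM (SD, n = 3) in wild-type and 744 ± 165 in DdblGata1 libraries. When adjusted over the list alone, Zfp36, Socs3 and Klf6 (edgeR adjusted p 0.0238) and Egr1 and Ier2 (0.0435) rose. DESeq2 called 4 members higher. Camera called the list higher with an adjusted p of 7.89e-11 (adjusted p = 0.563 with an estimated correlation). Glucocorticoid response genes were called higher too (camera adjusted p 5.34e-06; adjusted p = 0.602 with an estimated correlation). Of its 13 genes, Cebpd rose from 25.6 ± 3.93 to 54.3 ± 16.0 CPM when adjusted over the list alone (edgeR adjusted p 0.0252), and DESeq2 called Cebpd and Errfi1 higher. DdblGata1 replicates 9 and 10 carried this, with list levels of 5.42 and 5.95, while DdblGata1 replicate 4 had 5.0, within the wild-type range of 4.49 to 5.05. Errfi1 had 41.5 CPM in DdblGata1 replicate 4, 110 and 170 in DdblGata1 replicates 9 and 10, and 39.4 to 41.3 in wild-type libraries. Matrix proteases and their inhibitors were called higher by camera (adjusted p 0.00233; adjusted p = 0.663 with an estimated correlation). The proteases Htra1, Adamts5 and Plau rose by 0.72, 1.24 and 1.02 on the log2 scale when adjusted over that list alone (edgeR adjusted p 0.0498 for each). The camera adjusted p of the protease list was 0.212 without wild-type replicate 1 and 0.0948 without DdblGata1 replicate 4.

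Oxidative phosphorylation genes were lower in DdblGata1 libraries, 45 of 46 by value, with a median log2 fold change of -0.38. The list level was 6.34, 6.04 and 5.76 in wild-type replicates 1, 3 and 4. In DdblGata1 replicates 4, 9 and 10 it was 5.57, 5.83 and 5.68, so the groups overlapped and wild-type replicate 1 was highest. Atp5o, a subunit of ATP synthase, had 142 ± 25.4 CPM (SD, n = 3) in wild-type and 90.8 ± 9.34 in DdblGata1 libraries, and DESeq2 called it lower (adjusted p 0.0466). Sdhc, Atp5d and Cyc1 had values of -0.59, -0.64 and -0.61. Camera called the list lower with an adjusted p of 1.49e-11 (adjusted p = 0.602 with an estimated correlation), while 0 members passed edgeR adjusted over the list alone and 13 were lower at an unadjusted p under 0.05. Cholesterol synthesis genes were lower in all 22 cases by value (camera adjusted p 2.84e-07; adjusted p = 0.602 with an estimated correlation). Fdps, an enzyme of the pathway, had a log2 fold change of -0.65 ± 0.27 (SE). The level of the cholesterol list in DdblGata1 replicate 4 was 5.66, within the wild-type range of 5.58 to 5.71, against 5.07 and 4.70 in DdblGata1 replicates 9 and 10. Proliferation genes were called lower (camera adjusted p 0.00128; adjusted p = 0.602 with an estimated correlation), with DESeq2 calling 1 of 39, Rrm2, a ribonucleotide reductase subunit (-0.61, adjusted p 0.0426). Without DdblGata1 replicate 9 the camera adjusted p of the proliferation list was 0.131.

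2 further metabolic lists were called lower by narrower margins. Hypoxia and glycolysis genes had a camera adjusted p of 0.0406 (adjusted p = 0.602 with an estimated correlation), and the glycolytic enzyme Eno1 had a log2 fold change of -0.40 ± 0.13 (SE, n = 3). That call was lost without wild-type replicate 3 (0.15) and without DdblGata1 replicate 4 (0.0694), 9 (0.0609) or 10 (0.112), and with a filter of at least 1 CPM in 3 libraries (0.0595). The 12 measured mitochondrially encoded genes had a camera adjusted p of 0.0247 (adjusted p = 0.737 with an estimated correlation) and a median log2 fold change of -0.32, with -0.51 ± 0.21 for mt-Cytb. Here the call was lost without wild-type replicate 3 (0.489) and without DdblGata1 replicate 4 (0.376) or 9 (0.0823).

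Markers of cell types outside the sort gate were measured as well. Epithelial genes were lower by value in DdblGata1 libraries in all 24 cases, and camera called them lower (adjusted p 4.42e-04; adjusted p = 0.737 with an estimated correlation). Their level was 5.61 in wild-type replicate 1 against 3.16 to 3.86 in the other 5 libraries, and without wild-type replicate 1 the list was called higher instead (adjusted p 0.0377). Lgals4, an epithelial lectin, had 126 ± 142 CPM (SD, n = 3) in wild-type and 47.0 ± 6.96 in DdblGata1 libraries, and the Lgals4 log2 fold change went from -1.42 to 0.07 without wild-type replicate 1. Antigen presentation genes were also called lower (camera adjusted p 0.00433; adjusted p = 0.663 with an estimated correlation), with 0 members at an unadjusted p under 0.05 in edgeR and 0 called by DESeq2. Wild-type replicate 1 again had the highest level, 5.23 against 4.07 to 4.50, and without it the adjusted p was 0.36, and 0.341 with surrogate variables. Erythroid genes were called lower (camera adjusted p 0.00109; adjusted p = 0.602 with an estimated correlation). DdblGata1 replicate 4 had the lowest level of these genes, 1.80 against 3.40 to 4.63, and without it the adjusted p was 0.0948. Enteric neuron genes were called higher (camera adjusted p 0.0268; adjusted p = 0.737 with an estimated correlation), with Vip, a neuropeptide gene, at 0.89 ± 0.26 (SE). The neuron call was lost without wild-type replicate 1 (0.764) and without DdblGata1 replicate 4 (0.514).

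Of the 12 eosinophil markers in that list only 3 were measured, all near the lower limit of the table. Alox15, a lipoxygenase that macrophages also make, fell from 1.32 ± 0.529 to 0.171 ± 0.101 CPM (SD, n = 3) and Ccr3 from 0.722 ± 0.372 to 0.227 ± 0.0531 when adjusted over the list alone (edgeR adjusted p 0.00552 and 0.0358). Gata2, which other blood cells also express, had a log2 fold change of 1.63. Camera called the list lower (adjusted p 0.0406; adjusted p = 0.602 with an estimated correlation). The call was lost without wild-type replicate 1 (0.121) or 3 (0.106) and without DdblGata1 replicate 4 (0.0948) or 10 (0.238), and with surrogate variables (0.316) or fragment length (0.0789) as covariates.

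Among lists that camera did not call, single members passed when adjusted over the list alone by edgeR. Fgf10 rose in the list of angiogenic and lymphangiogenic factors (adjusted p 0.00229), and Cd55 in the complement list (0.00862). The cholesterol exporter Abca1 rose by 1.51 and the lipase Lpl by 1.46 on the log2 scale in the list of lipid handling (0.0356 for both). In the mesothelium list Wt1 rose by 0.94 and Slpi fell by 1.28 (0.0151 for both), and in the skeletal muscle list Ckm fell by 1.17 (0.0458). Adjusted p-values of camera were 0.177 for the angiogenic, skeletal muscle and leukocyte lists, 0.068 for complement and for exocrine pancreas, and 0.95 for lipid handling. Signalling lists had 0.663 for TGF-beta, 0.95 for BMP, 0.124 for Hedgehog, 0.183 for Wnt, 0.42 for Notch, 0.882 for YAP and TAZ targets, 0.174 for retinoids and 0.0968 for growth factors. Matrix lists had 0.882 for interstitial matrix, 0.265 for basement membrane and 0.115 for integrins. Immune and stress lists had 0.28 for type I interferon, 0.233 for type 2 cytokines, 0.882 for lymphoid-tissue stroma, 0.332 for heat shock and 0.796 for the unfolded protein response. The remaining cell type lists had 0.115 for enteric glia, 0.663 for blood and 0.554 for lymphatic endothelium, 0.803 for mesothelium, 0.235 for macrophages, 0.623 for lymphocytes and 0.332 for adipocytes. Ribosomal proteins (0.417) and the circadian clock (0.311) completed the set. Exocrine pancreas genes stood highest in wild-type replicate 4 (4.03) and DdblGata1 replicate 4 (4.72), against 2.18 to 3.12 in the other 4 libraries. Camera called that list higher with surrogate variables (9.69e-10; adjusted p = 0.495 with an estimated correlation), with fragment length (0.00157), with a filter of at least 1 CPM (0.0418), and without wild-type replicate 4 (1.52e-05) or DdblGata1 replicate 9 (8.18e-05) or 10 (0.00173), while without DdblGata1 replicate 4 its direction was downward (0.607). Enteric glia genes were called lower without wild-type replicate 1 (5.19e-08) and with surrogate variables (1.89e-05; adjusted p = 0.495 with an estimated correlation). With all 6 libraries, no covariate and an estimated correlation the adjusted p of both lists was 0.789. Without 1 library and with the preset correlation, other lists were called as well: interstitial matrix (0.0494), integrins (0.0128), Hedgehog (0.0249) and retinoids (0.00789) lower, and adipocytes (0.0249) and heat shock (0.0441) higher, without wild-type replicate 1. With an estimated correlation and all 6 libraries their adjusted p-values were 0.956, 0.602, 0.602, 0.737, 0.81 and 0.829, in the same order. Without wild-type replicate 3 these were basement membrane (0.0303; 0.822 with an estimated correlation and all 6 libraries) and growth factors (0.0127; 0.663) higher and type I interferon (0.0092; 0.867) and macrophages (0.0303; 0.829) lower. Without wild-type replicate 4 they were the angiogenic (0.0209, against 0.737 with an estimated correlation and all 6 libraries) and complement (0.0116, against 0.656) lists higher and leukocytes (0.0123, against 0.737) and macrophages (0.0378, against 0.829) lower. Without DdblGata1 replicate 9 complement was called higher (0.0392), and without DdblGata1 replicate 10 heat shock was called higher (0.00857) and type I interferon lower (0.0436), against 0.656, 0.829 and 0.867 with an estimated correlation and all 6 libraries. With surrogate variables integrins (0.0494), Hedgehog (0.0138) and retinoids (0.0478) were called lower and heat shock (0.00981) higher, with adjusted p-values of 0.495 for the first 3 and 0.682 for heat shock under an estimated correlation. With a filter of at least 1 CPM complement (0.0371, against 0.656 with an estimated correlation and no such filter) was called higher.

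In all, camera called 19 of 51 lists, 5 higher and 14 lower, and 32 were not called. With an estimated correlation 0 lists passed, the lowest adjusted p was 0.451 and 4 lists had an unadjusted p under 0.05. The rotation test fry called 0 lists, with a lowest adjusted p of 0.0538. Lists of mast cells and basophils, neutrophils and megakaryocytes had fewer than 3 measured genes and were not tested by camera or fry. In the exact two-sided permutation test of the mean level per library, 3 against 3 libraries cannot give a p under 0.1. That smallest value was reached by the PDGFRA-high, Hedgehog, inflammatory, immediate early, hypoxia, pericyte, neutrophil and skeletal muscle lists, and levels of the 14 other lists that camera called overlapped between the genotypes. Median and mean log2 fold change differed in sign for the lymphoid-tissue stroma, unfolded protein, lipid handling, lymphatic endothelium, lymphocyte and adipocyte lists, where the test followed the mean. For interstitial matrix the median was 0.01, the mean 0 and the direction of the test downward.

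**Figure D4:**
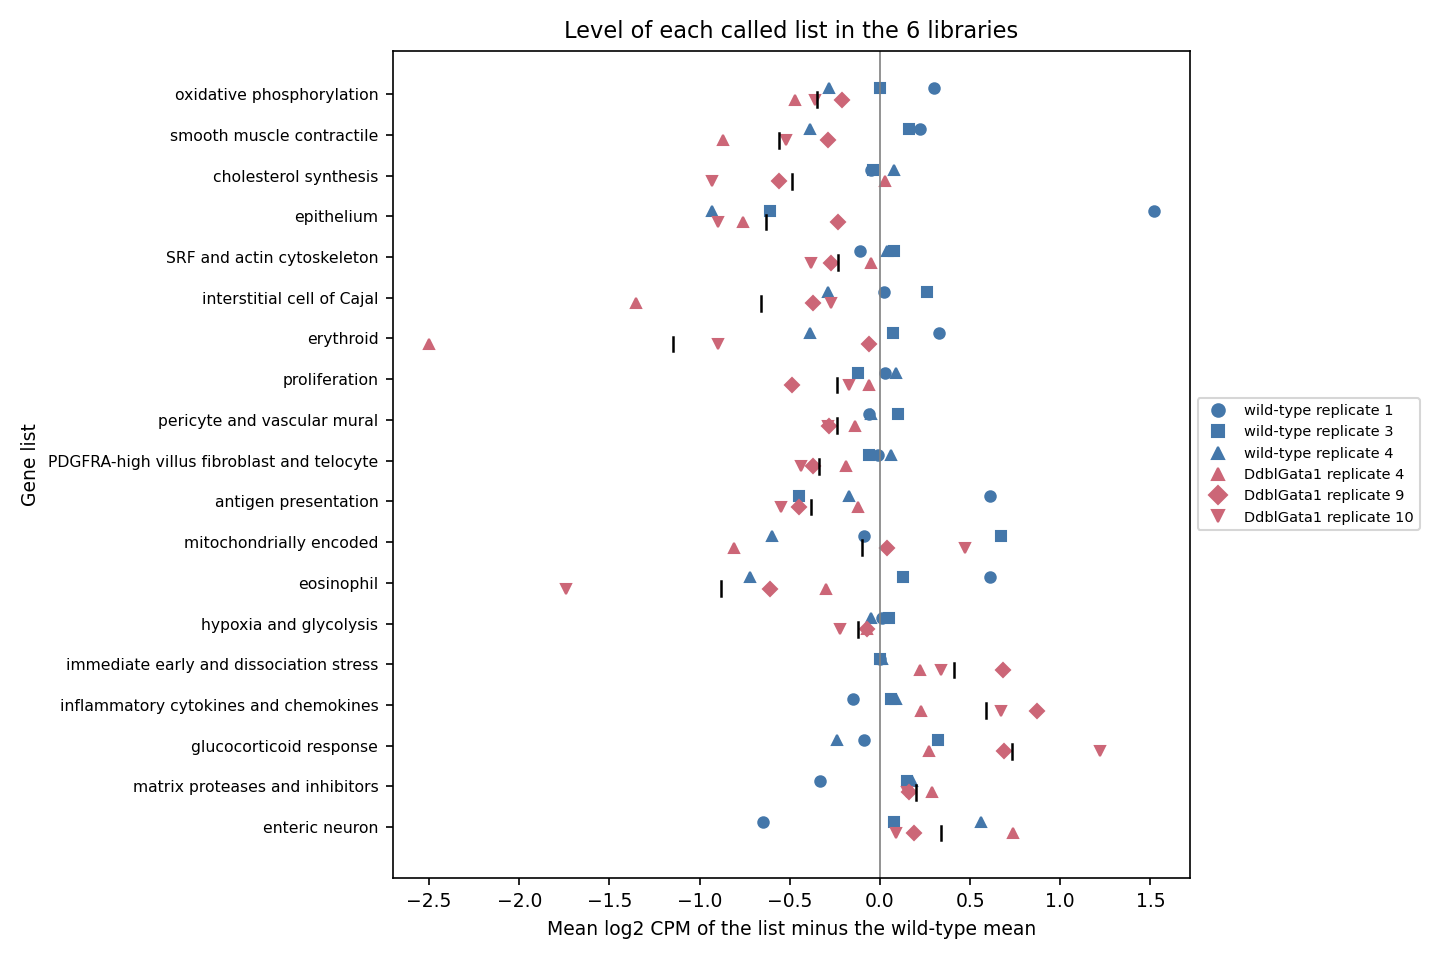
Mean log2 CPM of each of the 19 lists called by camera, minus the wild-type mean of the list (horizontal axis), 1 point per library, with a bar at the DdblGata1 mean (n = 3 per group). In the epithelium list wild-type replicate 1 stands far to the right of the other libraries, and in the inflammatory list all 3 DdblGata1 libraries lie to the right of all 3 wild-type libraries.

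Transcript usage was compared to see whether the genotypes differ in which isoforms a gene produces. Matn4, a matrix protein, gave 43.3% ± 23 (SD, n = 3) of its estimated counts to transcript Matn4-202 in wild-type libraries and 0% in DdblGata1 libraries (a count of 0 over the group allows up to 0.531%). Cnot6l, a deadenylase, gave 0% (up to 0.0366%) and 11.3% ± 5.10 to Cnot6l-202. Rbck1, a component of the linear ubiquitin ligase, gave 10.4% ± 4.4 and 0.1% ± 0.10 to Rbck1-201. In Fosb and Canx the called transcripts, Fosb-207 and Canx-202, took 0.4% and 0.5% in wild-type libraries. The gene-level Simes test of diffSpliceDGE in edgeR called 24 of 9447 genes, with adjusted p-values of 0.00953 for Cnot6l, Matn4 and Fosb and 0.0136 for Canx and Rbck1. In these 24 genes 24 transcripts were called, and for 22 of them every library of 1 genotype had fewer than 3 estimated counts. How the counts of such transcripts were assigned carries an uncertainty that was not estimated here. The count was 2 without DdblGata1 replicate 9 (Cnot6l and Rps6kc1, the latter singled out after its values were seen), 8 without wild-type replicate 4, 10 without DdblGata1 replicate 10 and 70 without DdblGata1 replicate 4. Among transcripts with at least 10% of their gene's counts in 3 libraries diffSpliceDGE called 0 of 6567 genes, with 52 at an unadjusted p under 0.05. The F test of all transcripts called 47. In simulated data of the observed dispersion the Simes test made 20 false calls, close to the 24 genes called here. Every other split of the libraries into 3 and 3 gave more genes, 28 to 381. The 24 calls therefore do not set the genotypes apart from other groupings.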

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

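Chosen only after the results were seen were the tests of wild-type replicate 1, the SRF quartile and the leukocyte and heat shock lists. Those of the level of DdblGata1 replicate 4, the neighbour pairs and the ranking of splits were chosen then too. So were the fits with surrogate variables or fragment length. The camera runs with each library left out or with an estimated correlation were planned. The tests of smooth muscle genes outside the contractile list and of the surroundings of Gata1 were fixed before their own values were seen. The bounds for the leukocyte level, for DdblGata1 replicate 4 and for the pairs of neighbours, and the family given to Mndal, were also set, and in part reset, after these values were seen.

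5 genes that the gene table leaves out had, in the transcript files, at least 10 estimated counts in every DdblGata1 library and more than in any wild-type library (transcripts that the comparisons do not use). The lowest DdblGata1 and highest wild-type values were 10 and 9 for Ttc9b, 10 and 4 for Tpte, 10 and 9 for Plac1, 10 and 6 for Fam196a and 21 and 20 for AC110730.1. Such genes numbered 5 of the 78 outside the table with at least 10 counts in 3 libraries, and the reverse order held for 8, where chance places 5% in each direction, so they do not stand out from chance.

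The smooth muscle contractile genes were lower in DdblGata1 libraries. The camera call did not need wild-type replicate 1, since without it the list was still called lower (adjusted p 4.18e-09 with the preset correlation). Over all 6 libraries left out in turn the camera adjusted p was 3.16e-20 to 2.81e-04. With this correlation every grouping of these libraries called lists, so a kept call excludes little. The levels left without wild-type replicate 1 overlapped. They were 8.93 and 8.38 in wild-type replicates 3 and 4, and 7.90, 8.48 and 8.25 in DdblGata1 replicates 4, 9 and 10. Of 16 smooth muscle genes outside the contractile list, 14 were lower, with a median log2 fold change of -0.33 and quartiles -0.55 and -0.19. The set mixed receptors, channels and RNA-binding proteins with other genes, among them Hhip, Npnt, Itga8 and Ppp1r12b, a subunit of myosin phosphatase. Its receptor and channel genes ranged from -1.53 for P2rx1 to 0.90 for Chrm3. The most abundant genes of the set, Ppp1r12b and Npnt, had 442 and 212 CPM in wild-type and 302 and 156 in DdblGata1 libraries. Fewer smooth muscle cells among the sorted cells would lower such genes. The podoplanin gate should largely exclude this type, yet contractile genes were abundant in wild-type libraries. Their mean log2 CPM was 8.38 to 8.99 there, and Des had 861 CPM. The set does not settle whether such cells were fewer, because it is not free of genes of contraction. Weaker SRF activity in cells of unchanged type stays open, because the upper quartile of the SRF and actin list, -0.048, only restates that 19 of its 23 genes were lower and tests nothing further. Hhip, Npnt and Itga8 also belong to other lists, and an effect of the genotype, which the design confounds with these explanations, was not tested. With an estimated correlation the contractile list had an adjusted p of 0.602, so the call, though not the fold changes, rests on the preset correlation.

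Inflammatory and immediate early genes were higher in DdblGata1 libraries, calls that rest on the preset correlation (adjusted p 0.451 and 0.563 with an estimated one). Whether DdblGata1 replicates 9 and 10 alone set this cannot be told apart. The level of the immediate early genes in DdblGata1 replicate 4 was 7, against 6.78, 6.78 and 6.79 in wild-type. It stood 28.9 wild-type SD above the wild-type mean, with 14 of 24 genes above every wild-type library. That SD was only 0.01, from 3 libraries, and the bound was set after the values were seen. The level of the inflammatory genes in DdblGata1 replicate 4 was 4.10, against 3.72, 3.93 and 3.96 in wild-type. It stood at 1.69 wild-type SD, with 12 of 22 genes above every wild-type library. Leukocytes among the sorted cells, which the CD45 gate should remove, stay open: the leukocyte list had a median log2 fold change of -0.44, but near the lower limit, at 1.69, 0.92 and 0.30 log2 CPM in wild-type replicates 1, 3 and 4 and 0.88, 0.52 and 0.01 in DdblGata1 replicates 4, 9 and 10 (exact permutation p 0.4), so that wild-type replicate 1 carried the difference. Stress while the tissue was dissociated could raise the same genes and stays open: heat shock genes were not called higher by camera (adjusted p 0.332; 0.829 with an estimated correlation), but were without wild-type replicate 1 (0.0441), without DdblGata1 replicate 10 (0.00857) and with the surrogate variables (0.00981; 0.682 with an estimated correlation), within a range of 0.00857 to 0.894 over all alternatives. No label gives the order or day of the dissociations, and an effect of the genotype was not tested.

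Several genes called by DESeq2 are neighbours: Ifi204, Mndal, Ifi211, Ifi203, Ifi202b and Ifi205 on chromosome 1, and Gm14387, Gm14443, Gm14288, Gm14296, Gm14421, Zfp970 and Gm14327 on chromosome 2, all higher in DdblGata1 libraries. Neighbours outside gene families were among the called genes too. Ncoa1, Fkbp1b and Atad2b on chromosome 12, Dpp4 and Fap on chromosome 2 and Abca1 and Fsd1l on chromosome 4 were higher. So was Ackr1, beside the Ifi genes, whereas Alox15 and Eno3 on chromosome 11 were lower. Pairs of called genes within 1 Mb and of the same direction numbered 40, against a median of 20 and an upper 95% bound of 31 in 10000 shuffles of the calls. Of the 40 pairs 24 were from 1 gene family, as reads shared between paralogs would need. Families were read from gene names, with all Zfp, Rik and numbered Gm genes pooled as 1 family and Mndal counted with the Ifi genes. With Mndal left out of the Ifi genes the count was 19. The 16 others (21 with Mndal left out, permutation p 0.44) lay within the shuffled range of 11 to 31 (permutation p 0.83). This leaves a linked stretch of DNA that differs between the strains open, since a stretch confined to such a cluster would give family pairs too. Within 10 Mb of Gata1, 6 of 57 genes had an unadjusted p under 0.05 in edgeR (odds ratio 1.03, 95% interval 0.36 to 2.4, Fisher's exact p 0.829), which leaves DNA carried along with the mutation open. An effect of the genotype on these genes was not tested.

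The 10 splits of the 6 libraries are too few for a share under 0.05. By edgeR the real split gave 0 genes and the highest other split 12; since any split gives at least 0, the count of 10 of 10 was certain beforehand and carries no information. At an unadjusted p under 0.05 edgeR gave 1564 genes for the real split and 1767 for the highest other, and 2 of 10 splits gave as many. DESeq2 gave 214 genes for the real split and 405 for the highest other, the same split as that with 1767, which sets wild-type replicate 1 and DdblGata1 replicates 9 and 10 against the rest; 2 of 10 splits gave as many. For gene lists camera gave 19 and 22, and 4 of 10 splits gave as many. With the preset correlation the other splits gave 12 to 22 lists, so every grouping of these libraries called lists. The number of called lists therefore does not set the genotypes apart from other groupings. With an estimated correlation each split gave 0 lists. Transcript usage gave 24 genes for the real split and 381 for the highest other, and 10 of 10 splits gave as many. The split with 381, which also gave edgeR's 12, sets the 3 libraries with fragment lengths of 363 or 364 bases against those with 326 to 341, a structure of the samples; with fragment length as a covariate 17 genes were called.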

How the results depend on the processing

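The surrogate variables, fragment length, unscaled transcript sums and DESeq2 without each library were chosen after seeing the data. The named genes were taken from these same data by smallest p, some also for non-overlapping groups. A reversed direction was therefore unlikely beforehand, and a kept one says little about robustness. Of 2522 values of 110 named genes under 23 alternatives, 2521 kept their direction. The exception was the Lgals4 log2 fold change without wild-type replicate 1 (0.07; range without 1 library -1.84 to 0.07). Of 265 values of the 19 called lists, 182 kept their call, 80 lost it in the same direction and 3 turned, all for epithelium: its adjusted p was 0.961 with surrogate variables, 0.983 with these and an estimated correlation, and 3.07e-10 to 0.0377 without 1 library, upward at 0.0377 without wild-type replicate 1.

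The edgeR count of 0 genes (1564 at an unadjusted p under 0.05) was 0 under every edgeR and limma alternative and 0 to 1 without 1 library, against 214 by DESeq2, 449 by DESeq2 with surrogate variables and 221 with fragment length. DESeq2 itself gave 43 to 1025 genes without 1 library. Called lists went from 19 to 0 with an estimated correlation, by fry, and with surrogate variables and an estimated correlation. They went to 12 to 25 without 1 library. An estimated correlation takes into account how members of a list varied together between these libraries, which the preset one does not. Transcript usage went from 24 genes to 47 with the F test, 0 with the 10% filter and 2 to 70 without 1 library. The cause of these changes was not tested. The filter of no minimum moved nothing, since filterByExpr removed no gene, and sex as a covariate was not run. No paired analysis was possible because the genotypes share only 1 replicate number. In simulated genes under the median of 21.7 CPM edgeR recovered 1 of 27 changes of 2-fold and 17 of 23 of 8-fold, against 13 of 23 and 27 of 27 above it.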

Other observations

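Further members of the lists have a known place in the gut wall. Sema3c, a guidance factor of mesenchyme, had 302 ± 109 CPM (SD, n = 3) in wild-type and 619 ± 123 in DdblGata1 libraries, and Edn1, a peptide that contracts vessels, had 4.21 ± 1.15 and 10.6 ± 3.86; DESeq2 called both higher (adjusted p 0.0442 and 0.0274), and edgeR did not (0.398 and 0.384). Kit, the receptor of interstitial cells of Cajal, had 203 ± 66.6 and 107 ± 60.2 CPM, and neither tool called it (adjusted p 0.525 by edgeR and 0.355 by DESeq2), whereas DESeq2 with the surrogate variables called it lower (log2 fold change -1.50, adjusted p 2.15e-11). Its CPM in DdblGata1 replicate 4 was 39.1, against 153 and 129 in DdblGata1 replicates 9 and 10 and 128 to 255 in wild-type libraries. Hhip and Ppp1r12b, mentioned above, were chosen after the contractile result was seen. Hhip, a Hedgehog antagonist of villus mesenchyme, had 73.1 ± 3.08 and 50.9 ± 9.26 CPM, and Ppp1r12b is a subunit of myosin phosphatase. Both were called lower by DESeq2 with the surrogate variables (adjusted p 0.00374 and 0.00776), which were estimated from the same libraries, and not without them (0.168 and 0.146).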
